A study of Homo sapiens with 12 samples.

How the data were processed

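Total RNA from MDA-MB-231 cells was measured on 12 bead arrays, 1 per sample, with 3 arrays in each of 4 groups. The groups came from the sample titles and from the transfection and treatment labels. Per the labels, RNA was extracted with the mirVana kit, total RNA was amplified and labelled with biotin with the TotalPrep kit, and the values of 48803 probes were exported with BeadStudio, whose version was not given in the sources used here. The authors deposited a table of intensity per probe and array that had not been normalized, on a linear scale. It held no detection p-value, bead count, negative control or background estimate. The authors also deposited a series table of processed log2 values, whose scale and normalization were not stated. Compared with the intensities, that table equalled the log2 of quantile-normalized intensities without background correction, with a median of 6.02 in each array, so its direction, scale and centring were known from this comparison.

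The intensities were corrected for background with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50, then quantile-normalized between arrays and taken to log2. The normexp method needed no detection p-values or negative controls, and this setting had been chosen before the data were examined for a table without them, as had the groups, comparisons, tests, gene lists and rule for named genes. Probes were kept where their mean log2 intensity over the 12 arrays was above the median of all probes (6.15), which left 24401. Probe names were updated through the accessions of an NCBI RefSeq table of human genes (assembly GRCh38.p14). Of the 48803 probes, 26251 were named by accession, 2020 by current symbol and 992 by an older symbol. The symbol of the file was kept for 6887, and 12653 had none. No coordinates were used. For each gene the probe with the highest mean was taken, which gave 15846 genes. Opposite calls by different probes of a gene were counted among the 3981 genes with more than 1 probe: 7 and 39 genes for siFOXM1 without and with doxorubicin, 102 and 122 for doxorubicin in siLuc and siFOXM1 cells, and 5 for the interaction.

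One linear model of the 4 group means was fitted to all 12 arrays with lmFit and eBayes, with 8 residual degrees of freedom and 10.7 prior ones. Its 5 contrasts were siFOXM1 against siLuc without and with doxorubicin, doxorubicin against none in siLuc and in siFOXM1 cells, and the interaction, which is the siFOXM1 effect with doxorubicin minus that without it. Tests were two-sided, and a gene was past the threshold at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Errors of log2 changes are standard errors (SE) of the fit with 3 arrays per group.

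Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one, and p-values were adjusted over 18 lists and 5 contrasts (90 tests). The lists were mitosis and G2/M, G1/S and DNA replication, homologous recombination and Fanconi anaemia, other DNA repair, p53 targets, AP-1 and immediate early, NF-kB and inflammatory cytokines, interferon-stimulated, histone, endoplasmic reticulum stress and ATF4, heat shock, cholesterol synthesis, apoptosis regulators, mesenchymal and invasion, ribosomal proteins, housekeeping, and markers of luminal epithelial lines and of blood cells. Each needed at least 5 measured genes. Of 38 list calls, 28 held with an estimated correlation, and the other 10 are given with that p where they are reported. For the 28, the p printed is that of the preset correlation unless stated otherwise. With an estimated one (0.0888 for mitosis and 0.0655 for interferon-stimulated genes) their p-values were larger. Mitosis genes for siFOXM1 with doxorubicin went from 1.31e-40 to 0.00372, and the smallest adjusted p of the 90 camera tests was 0.00143. No list call held with an estimated correlation and median scaling together. The text could name FOXM1, the replication factor C genes, the 6 largest rises and falls per comparison among genes past the threshold whose groups did not overlap (5 each way for the interaction), and up to 3 members per list and comparison. Symbols that were only an accession, locus number, open reading frame or clone were left out, and the text names part of what the rule allowed.

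The fit was tested on simulated arrays with the means and spread of the 15846 genes, of which 200 were changed. For siFOXM1 without doxorubicin it recovered 73.1% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes. With doxorubicin the shares were 74.6%, 98.5% and 100%. For doxorubicin they were 82.1%, 97.0% and 100% in siLuc cells and 85.1%, 100% and 100% in siFOXM1 cells. For the interaction 41.8%, 88.1% and 100% were recovered. The real comparisons had 2220 to 8720 genes past the threshold, far more than 200, and the simulated noise was independent between genes. The shares recovered there may therefore differ. The runs above let no gene fall below the dim end of the range, and a further run let any gene fall. Over all its 4-fold changes, rises and falls of bright and dim genes together, sizes were understated on average. The mean was 0.141 log2 for siFOXM1 without doxorubicin and 0.185 with it. It was 0.255 and 0.258 for doxorubicin in siLuc and siFOXM1 cells, and 0.175 for the interaction. How far falls of dim genes alone were understated was not worked out. All these runs started from gene values after background correction. Any shrinkage of changes by that correction and its offset is therefore in neither the shares nor the means, and was not measured. No depth exists for arrays, and their number limits the precision.

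Alternatives were no background correction, an offset of 16, scaling of each array to a common median, the deposited log2 table, no filter on dim probes, a filter at the 75th percentile, every probe in place of 1 per gene, only the groups compared, the replicate number as a block, array weights, a trended and robust fit, a fold of at least 1.5, and leaving out each array in turn. For the interaction, residuals of the arrays were also permuted 99 times with the additive effects of siFOXM1 and doxorubicin kept, once with residuals of the additive model and once with those of the group means. Python 3.11.15 and matplotlib 3.10.9 drew the figures. Probes without a symbol were left out of the comparisons, and their counts are given at the end. Lists of very long genes and of histone gene classes, used in the closing tests, were written after the results were seen.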

Results

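Gene expression was measured in MDA-MB-231, a human breast cancer cell line without oestrogen receptor, after transfection with siLuc, the control, or with siFOXM1. FOXM1 is a forkhead transcription factor that drives genes of the G2 phase and mitosis. Each transfection was measured without and with doxorubicin, an anthracycline that traps topoisomerase II and breaks DNA, which made 4 groups of 3 arrays. The treatment label of all 12 samples also held the word doxycline, and no dose or time was given in the sources used here. The labels named no other transfection against FOXM1 and none that restored it. Loss of FOXM1 therefore cannot be told apart from other effects of the siFOXM1 transfection in any of the changes below. The comparisons asked what siFOXM1 changed without and with the drug, what the drug changed in either transfection, and where those effects differed.

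Before normalization, the mean intensity of an array was 507 ± 60.7 (SD, n = 3) in siLuc, 440 ± 42.6 in siFOXM1, 401 ± 17.1 in siLuc with doxorubicin and 361 ± 30.6 in siFOXM1 with doxorubicin. Arrays of a group correlated at 0.988 to 0.994 over all probes, lowest in siFOXM1 with doxorubicin. The labels did not say that the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. All changes are relative to quantile normalization, which gives each array the same distribution. With each array scaled to a common median in its place, the median change of all genes was -0.0825 log2 for siFOXM1 without doxorubicin and -0.0966 with it, -0.116 for doxorubicin in siLuc cells and -0.132 in siFOXM1 cells. List medians given with median scaling include such a shift. One that turned to a value smaller than the median of all genes did not fall relative to all genes. The shift differed between lists. For doxorubicin in siLuc cells, housekeeping genes went from -0.12 to -0.44, ribosomal protein genes from -0.26 to -0.58 and blood cell markers from 0.26 to 0.20. A larger turn, or a larger fall than with quantile normalization, may thus be part of this shift.

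FOXM1 itself was low in every siFOXM1 array. Its log2 intensity was 9.45 to 9.67 in the 3 siLuc arrays and 7.23 to 7.55 in the 3 siFOXM1 arrays, and with doxorubicin 9.81 to 9.88 and 7.10 to 7.77. It fell without doxorubicin (-2.17 ± 0.13 log2, 22.3% of the siLuc level left, adjusted p = 3.25e-09) and with it (-2.35 ± 0.13, 19.6% left, adjusted p = 4.36e-10). A second FOXM1 probe gave -1.49 and -1.71. Doxorubicin left FOXM1 short of the threshold in siLuc cells (0.27 ± 0.13, adjusted p = 0.102) and in siFOXM1 cells (0.09 ± 0.13, adjusted p = 0.621), and the interaction was -0.18 ± 0.19 (adjusted p = 0.598).

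**Figure D1:**
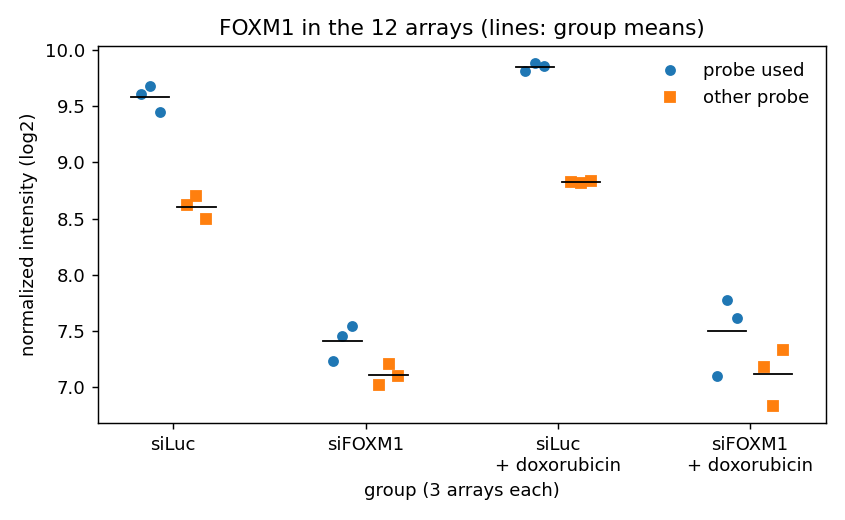
Normalized log2 intensity of both FOXM1 probes in each array, by group, with group means as lines (3 arrays each). For the probe used, means were 9.58 in siLuc, 7.41 in siFOXM1, 9.85 in siLuc with doxorubicin and 7.50 in siFOXM1 with doxorubicin.

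Without doxorubicin, siFOXM1 lowered genes of mitosis and of cholesterol synthesis and raised interferon-stimulated genes. These calls held with median scaling and with an estimated correlation (camera adjusted p = 0.00964, 0.00528 and 0.00964 with the latter). They did not hold with both together (adjusted p = 0.453, 0.311 and 0.407), a pair of settings under which no list call of any comparison held. Of 73 mitosis and G2/M genes 45 fell and 0 rose, with a median of -0.39 log2 (53 fell adjusted over the list alone; camera adjusted p = 5.87e-23). With median scaling 54 fell, 0 rose and the median was -0.58. The centrosome kinase NEK2 fell by 1.31 ± 0.11, the spindle protein TROAP by 1.20 ± 0.09 and FAM83D, which brings a kinase to the spindle, by 1.12 ± 0.11. Of 24 cholesterol synthesis genes 17 fell and 0 rose (18 and 1 adjusted over the list alone; median -0.47, adjusted p = 2.82e-12). Among them were FDFT1, the squalene synthase (-1.48 ± 0.12), and the sterol sensor partner INSIG1 (-1.01 ± 0.10). Of 37 interferon-stimulated genes 19 rose and 0 fell (22 rose adjusted over the list alone; median 0.34, adjusted p = 1.02e-13), among them IFIT2 at 1.45 ± 0.10. With median scaling 13 rose, 0 fell and the median was 0.21.

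Genes of DNA replication fell as well. Of 57 G1/S and DNA replication genes 17 fell and 1 rose (24 and 2 adjusted over the list alone; median -0.22, adjusted p = 3.20e-06), with the chromatin remodeller HELLS at -0.68 ± 0.09 and the thymidine kinase TK1 at -0.60 ± 0.09. With median scaling 26 fell, 0 rose and the median was -0.41. Of the replication factor C genes, whose products load the sliding clamp, RFC1 fell by 0.61 ± 0.09 and RFC5 by 0.55 ± 0.09. RFC2 (-0.45 ± 0.12, adjusted p = 0.0145) was no longer past the threshold without siLuc replicate 1 (adjusted p = 0.0760) or siFOXM1 replicate 3 (adjusted p = 0.108). RFC4 (-0.35 ± 0.10, adjusted p = 0.0263) lost its call with an offset of 16 (adjusted p = 0.0598) and without siLuc replicate 1 or 2 or any 1 of the 3 siFOXM1 replicates (adjusted p 0.0608 to 0.135). RFC3 stayed at -0.06 ± 0.10 (adjusted p = 0.747). Of 32 homologous recombination and Fanconi anaemia genes 7 fell (12 adjusted over the list alone; median -0.22, adjusted p = 5.51e-04), or 14 with a median of -0.31 under median scaling, among them UBE2T, the Fanconi ubiquitin-conjugating enzyme, at -0.62 ± 0.09.

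Smaller shifts were seen in stress and early response genes. Of 30 endoplasmic reticulum stress and ATF4 genes 7 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.15, or -0.32 with median scaling; adjusted p = 0.00793). The mTOR inhibitor DDIT4 fell by 0.61 ± 0.09 and the lipoprotein receptor VLDLR by 0.66 ± 0.10. Of 32 AP-1 and immediate early genes 8 rose and 3 fell, both over all genes and adjusted over the list alone (median 0.14, adjusted p = 0.0293), with the secreted matrix protein CCN1 at 0.74 ± 0.13 and the inhibitor of differentiation ID3 at 0.69 ± 0.10. This AP-1 call was lost with an estimated correlation (adjusted p = 0.0707 with an estimated correlation), with median scaling (2 rose and 4 fell, adjusted p = 0.151) and without siLuc replicate 1 or 2 (adjusted p = 0.0656 and 0.0529).

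Outside the lists, the largest rises among named genes were CPA4, a carboxypeptidase (3.52 ± 0.14, 11.5-fold), the secretory chaperone SCG5 (2.27 ± 0.11), the G protein regulator RGS7 (2.17 ± 0.14), the hair keratin KRT81 (1.96 ± 0.11) and the cytokine IL24 (1.87 ± 0.09). The largest falls after FOXM1 were TMEM71 (-1.57 ± 0.11), the cell cycle phosphatase CDKN3 (-1.54 ± 0.10), FDFT1, the proteasome lid protein SEM1 (-1.38 ± 0.11) and the complex I subunit NDUFA7 (-1.35 ± 0.14). In all, 2670 of 15846 genes were past the threshold, 1398 higher and 1272 lower, and 86 of them changed at least 2-fold (55 higher, 31 lower). Of the genes past the threshold 52.4% were higher, against 19.7% of 2421 with median scaling. The groups did not overlap for 36.4% of genes, where chance gives 10%.

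With doxorubicin present, siFOXM1 lowered nearly the whole cell cycle program and raised histone genes. Of 73 mitosis and G2/M genes 67 fell and 2 rose, the same counts adjusted over the list alone (median -1.10, adjusted p = 1.31e-40). Among those that fell were the spindle midzone protein PRC1 (-2.00 ± 0.10), TROAP (-1.84 ± 0.09) and the cyclin CCNB2 (-1.71 ± 0.10). Of 57 replication genes 52 fell and 0 rose, the same adjusted over the list alone (median -0.91, adjusted p = 4.50e-31). The primase PRIM1 (-1.58 ± 0.10), MCM10 (-1.58 ± 0.09) and the helicase subunit MCM6 (-1.55 ± 0.10) led these. With an estimated correlation the camera adjusted p was 0.00372 for mitosis and 0.00143 for replication genes. All 5 replication factor C genes fell: RFC1 by 1.03 ± 0.09, RFC2 by 0.73 ± 0.12, RFC3 by 1.24 ± 0.10, RFC4 by 1.20 ± 0.10 (adjusted p = 5.21e-08) and RFC5 by 1.54 ± 0.09.

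Repair genes fell as well. Of 32 homologous recombination and Fanconi anaemia genes 22 fell and 0 rose (22 and 1 adjusted over the list alone; median -0.51, adjusted p = 4.37e-11), led by the exonuclease EXO1 (-1.58 ± 0.09), UBE2T (-1.45 ± 0.09) and FANCG (-1.34 ± 0.09). Of 56 other DNA repair genes 16 fell and 3 rose, over all genes and adjusted over the list alone, with a median of -0.11 and a test short of the threshold (adjusted p = 0.0548). That test was past it with median scaling (23 fell, 1 rose, median -0.23, adjusted p = 0.0169), without siLuc replicate 3 of the doxorubicin group (adjusted p = 0.0401) and without siFOXM1 replicate 3 of that group (adjusted p = 0.0493). Its members PARP1 and PARP2, which sense DNA strand breaks, fell by 1.30 ± 0.10 and 1.13 ± 0.10.

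Among the groups that rose, 12 of 20 histone genes rose and 2 fell (13 and 3 adjusted over the list alone; median 0.82, adjusted p = 2.59e-07), with H2BC21 at 2.71 ± 0.14, H4C8 at 2.53 ± 0.11 and H2AC6 at 2.01 ± 0.11. Histone genes have near-identical copies, so which copy a probe measured is uncertain. Of 35 ribosomal protein genes 13 rose and 0 fell, the same adjusted over the list alone (median 0.21, adjusted p = 8.77e-04), with RPL7 at 0.72 ± 0.12, and with median scaling 1 rose and the median was 0.09. Of 27 NF-kB and inflammatory cytokine genes 9 rose and 4 fell (10 and 4 adjusted over the list alone; median 0.14, adjusted p = 0.0370), with the interleukin IL1B at 1.61 ± 0.10 and the chemokine CCL2 at 0.95 ± 0.12. This call was lost with an estimated correlation (adjusted p = 0.0707 with an estimated correlation), with median scaling (3 rose and 4 fell, median 0.03, adjusted p = 0.117), and without siLuc replicate 2 or siFOXM1 replicate 3 of the doxorubicin groups (adjusted p = 0.0568 and 0.0511).

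A further pair of lists was past the threshold, with medians that turned below 0 under median scaling by less than the median shift of all genes, -0.0966. Of 32 AP-1 and immediate early genes 8 rose and 1 fell, also adjusted over the list alone (median 0.18, adjusted p = 0.0140, and -0.04 with adjusted p = 0.355 under median scaling; adjusted p = 0.0525 with an estimated correlation). The transcription factors NR4A2 and JUND rose by 0.64 ± 0.10 and 0.56 ± 0.11, and KLF2 fell by 0.68 ± 0.10. Of 34 mesenchymal and invasion genes 9 rose and 1 fell, also adjusted over the list alone (median 0.13, adjusted p = 0.0271, and -0.02 with 3 higher, 3 lower and adjusted p = 0.0289 under median scaling; adjusted p = 0.0707 with an estimated correlation). The collagenase MMP1 rose by 2.12 ± 0.13, the stromelysin MMP3 by 2.47 ± 0.10 and the collagen COL6A1 by 0.63 ± 0.10. Without siLuc replicate 2 or siFOXM1 replicate 2 of the doxorubicin groups the adjusted p of this list was 0.0596 and 0.0574.

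The largest rises under doxorubicin were KRTAP3-2, a hair keratin-associated protein (2.91 ± 0.09, and 1.07 by a second probe), H2BC21, H4C8, MMP3, CPA4 (2.43 ± 0.14) and H4C5 (2.30 ± 0.11). After FOXM1, the largest falls were NDUFA7 (-2.05 ± 0.14), PRC1, TROAP, CCNB2 and CDKN3 (-1.69 ± 0.10). Past the threshold were 5124 genes, 2344 higher and 2780 lower, and 336 changed at least 2-fold (133 higher, 203 lower). Of those past it 45.7% were higher, against 18% of 4227 with median scaling. The groups did not overlap for 40.2% of genes, where chance gives 10%.

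The siFOXM1 effect differed with and without doxorubicin in 2220 genes by the interaction test, 855 higher and 1365 lower with the drug. Replication genes stood out: the effect was more negative with the drug in 43 of 57 and more positive in 0 (48 and 0 adjusted over the list alone; median interaction -0.79, adjusted p = 7.19e-29). PRIM1 had an interaction of -1.33 ± 0.14, MCM6 of -1.27 ± 0.14 and E2F2, a transcription factor of S-phase entry, of -1.65 ± 0.14. For RFC4 it was -0.86 ± 0.15 (adjusted p = 6.48e-04), for RFC5 -0.99 ± 0.12 and for RFC3 -1.17 ± 0.14, with -0.76 and -0.21 at its other probes. Of the mitosis genes 47 of 73 were more negative and 2 more positive (56 and 3 adjusted over the list alone; median -0.61, adjusted p = 5.64e-24), among them the kinetochore proteins CENPF (-1.54 ± 0.13) and NDC80 (-1.29 ± 0.12) and TOP2A (-1.45 ± 0.16), the topoisomerase that doxorubicin traps. The camera adjusted p of these interactions was 0.00143 for replication and 0.00964 for mitosis genes with an estimated correlation.

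Of the homologous recombination and Fanconi anaemia genes 15 of 32 had a negative interaction and 0 a positive one (16 and 0 adjusted over the list alone; median -0.37, adjusted p = 9.69e-08), with EXO1 at -1.35 ± 0.13 and FANCG at -1.32 ± 0.13. With median scaling 9 were negative, 0 positive and the median was -0.36. Among other DNA repair genes 13 of 56 were negative and 1 positive, also adjusted over the list alone (median -0.10, adjusted p = 0.0140), with PARP1 at -1.24 ± 0.14 and PARP2 at -0.85 ± 0.14. Interferon-stimulated genes, raised by siFOXM1 without the drug, had a negative interaction in 21 of 37 and a positive one in 0 (23 and 1 adjusted over the list alone; median -0.47, adjusted p = 3.33e-09), with IFIT2 at -1.50 ± 0.15 and the ubiquitin-like ISG15 at -1.05 ± 0.17. With doxorubicin the siFOXM1 effect on this list had a median of -0.11 (6 of 37 higher and 4 lower, also adjusted over the list alone; adjusted p = 0.989), and median, mean and test differed in sign. With median scaling 2 were higher, 12 lower and the median was -0.21.

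Positive interactions were found in histone genes, 10 of 20 against 1 negative (12 and 1 adjusted over the list alone; median 0.43, adjusted p = 5.08e-10), with H4C8 at 2.26 ± 0.15 and H2BC21 at 2.02 ± 0.19. Of cholesterol synthesis genes 8 of 24 were positive and 1 negative (9 and 2 adjusted over the list alone; median 0.28, adjusted p = 1.79e-04), with INSIG1 at 1.47 ± 0.13 and HMGCS1, the first dedicated enzyme of the pathway, at 1.04 ± 0.14. With median scaling 5 were positive, 0 negative and the median was 0.25. Under doxorubicin the siFOXM1 effect on that list had a median of -0.18 with 8 lower and 3 higher, also adjusted over the list alone (adjusted p = 0.147; 0.0356 with median scaling). Of endoplasmic reticulum stress genes 6 of 30 were positive and 1 negative, also adjusted over the list alone (median 0.21, adjusted p = 0.00637), with DDIT4 at 1.06 ± 0.13 and the chaperone HSPA5 at 0.97 ± 0.16. With median scaling 3 were positive, 0 negative and the median was 0.17. The ribosomal protein list (2 of 35 positive and 0 negative, 1 and 0 adjusted over the list alone; median 0.14, or 0.23 with median scaling; adjusted p = 0.0312) lost its call with an estimated correlation (adjusted p = 0.0998 with an estimated correlation) and without siLuc replicate 2 (adjusted p = 0.0529) or siFOXM1 replicate 2 of the doxorubicin group (adjusted p = 0.0642).

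The largest positive interactions were KRTAP3-2 (2.67 ± 0.13, and 1.05 by a second probe), H4C5 (2.31 ± 0.15), H4C8, MMP3 (2.08 ± 0.15) and H3C10 (2.05 ± 0.16). The largest negative ones were CACNA2D3, a calcium channel subunit (-1.81 ± 0.13), E2F2, the lipid receptor S1PR5 (-1.64 ± 0.15), suprabasin SBSN (-1.55 ± 0.23) and MPP4 (-1.55 ± 0.13). With median scaling 967 genes were past the interaction's threshold, 965 of them among the 2220 and in the same direction, and 29.3% were higher in place of 38.5%. Across genes, which are not independent replicates, the siFOXM1 effects without and with doxorubicin correlated at 0.477 (Pearson) and 0.397 (Spearman). Both were higher for 664 genes and both lower for 777, where independent lists would share 207 and 223. A further 108 rose without and fell with doxorubicin and 44 the reverse.

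**Figure D2:**
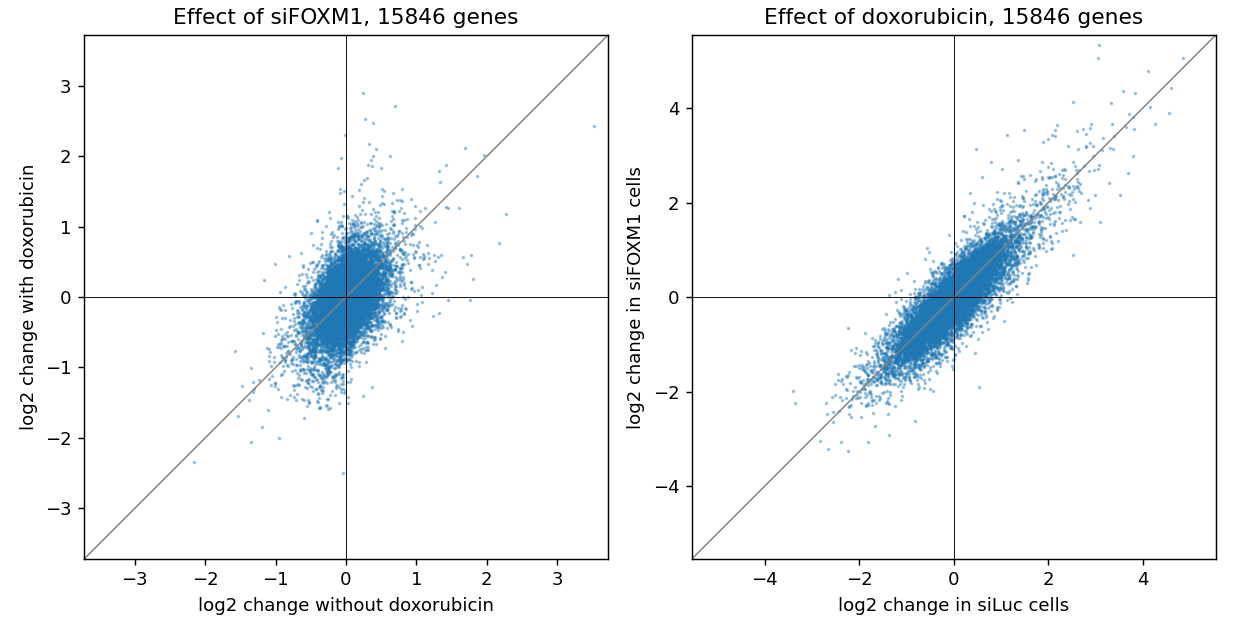
Log2 changes of 15846 genes, each a point, with the siFOXM1 effect without against with doxorubicin (left) and the doxorubicin effect in siLuc against siFOXM1 cells (right); the grey line marks equal changes. Spearman correlations were 0.397 and 0.816.

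Doxorubicin in siLuc cells raised histone, interferon-stimulated, immediate early and replication genes and lowered genes of mitosis and ribosomal proteins. The mitosis call was lost with an estimated correlation (adjusted p = 0.0869 with an estimated correlation), and the replication median was 0.02 with median scaling. Of 20 histone genes 13 rose and 4 fell (14 and 4 adjusted over the list alone; median 1.15, adjusted p = 1.39e-04), with H2AC18 at 3.84 ± 0.10, H4C8 at 3.08 ± 0.11 and H2BC21 at 3.06 ± 0.14. Of 37 interferon-stimulated genes 27 rose and 2 fell, also adjusted over the list alone (median 1.01, adjusted p = 1.51e-10), with IFI6 at 3.29 ± 0.10 and IFIT2 at 3.10 ± 0.10. Of 32 AP-1 and immediate early genes 17 rose and 7 fell, also adjusted over the list alone (median 0.40, adjusted p = 0.00236), and under median scaling 14 rose, 11 fell and the median was 0.10. The AP-1 subunits FOSB and FOS rose by 4.86 ± 0.19 and 3.65 ± 0.10, and the inhibitor of differentiation ID2 by 4.60 ± 0.14.

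Of 57 replication genes 30 rose and 3 fell (32 and 3 adjusted over the list alone; median 0.34, adjusted p = 7.69e-06), with the histone chaperone ASF1B at 2.63 ± 0.11, E2F2 at 2.53 ± 0.10 and TK1 at 2.42 ± 0.09. Under median scaling 21 rose, 10 fell and the median was 0.02. RFC5 rose by 0.96 ± 0.09. RFC2 (0.64 ± 0.12) and RFC3 (0.56 ± 0.10) were past the threshold with quantile normalization and not with median scaling (adjusted p = 0.0976 and 0.111). RFC4 stood at -0.04 ± 0.10 (adjusted p = 0.771), against -0.41 with adjusted p = 0.0216 under median scaling. Of 73 mitosis genes 53 fell and 9 rose (54 and 9 adjusted over the list alone; median -0.47, adjusted p = 1.22e-06; adjusted p = 0.0869 with an estimated correlation), and with median scaling 60 fell, 4 rose and the median was -0.82. The spindle protein DLGAP5 fell by 1.83 ± 0.11, the cyclin CCNF by 1.40 ± 0.16 and PSRC1 by 1.39 ± 0.10. Of 35 ribosomal protein genes 22 fell and 2 rose, also adjusted over the list alone (median -0.26, adjusted p = 3.08e-04), with RPS7 at -1.90 ± 0.10 and RPL5 at -0.95 ± 0.08. With median scaling 28 fell, 0 rose and the median was -0.58.

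Repair lists were short of the threshold in siLuc cells. Of 32 homologous recombination and Fanconi anaemia genes 9 rose and 7 fell, also adjusted over the list alone (median 0.00, adjusted p = 0.967), against 2 and 13 with a median of -0.19 under median scaling, with the recombinase paralog XRCC3 at 1.19 ± 0.11 and the break sensor NBN at -1.53 ± 0.12. Of 56 other DNA repair genes 21 fell and 7 rose, also adjusted over the list alone (median -0.12, adjusted p = 0.0642), and the test was past the threshold with median scaling (30 fell, 0 rose, median -0.43, adjusted p = 0.00772), without a filter (adjusted p = 0.0156) and without siLuc replicate 3 (adjusted p = 0.0428). The base excision enzyme NTHL1 fell by 1.97 ± 0.13.

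The largest rises were FOSB, ID2, the retinoid-binding protein CRABP2 (4.55 ± 0.12, 23.5-fold), CRISPLD2 (4.27 ± 0.10), VASN (4.15 ± 0.15) and the secreted glycoprotein RELN (4.12 ± 0.10). Among the largest falls were the organic anion transporter SLCO4A1 (-3.39 ± 0.15, 10.5-fold), the mitochondrial lipid enzyme TAMM41 (-2.82 ± 0.11), the methyltransferase SMYD3 (-2.71 ± 0.10) and GPSM1 (-2.66 ± 0.13). DMBT1 fell by 2.69 ± 0.12 at the probe used and stood at 0.11 at another. Past the threshold were 8441 genes, 4291 higher and 4150 lower, of which 1595 changed at least 2-fold (807 higher, 788 lower). Of those past it 50.8% were higher, against 29.2% of 7874 with median scaling. The groups did not overlap for 60.8% of genes, where chance gives 10%.

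In siFOXM1 cells doxorubicin lowered mitosis genes further and raised histone genes most. Of 73 mitosis genes 62 fell and 7 rose, also adjusted over the list alone (median -1.21, adjusted p = 1.45e-16), with DLGAP5 at -3.07 ± 0.11, the kinesin KIF20B at -2.27 ± 0.09 and CDCA3 at -2.18 ± 0.09. Of 20 histone genes 13 rose and 3 fell, also adjusted over the list alone (median 2.02, adjusted p = 7.43e-07), with H4C8 at 5.34 ± 0.11 (40.6-fold), H2BC21 at 5.07 ± 0.14 and H2AC18 at 4.33 ± 0.10. Of 32 AP-1 and immediate early genes 19 rose and 8 fell, also adjusted over the list alone (median 0.42, adjusted p = 8.77e-04), with a median of 0.06 under median scaling. FOSB rose by 5.05 ± 0.19 and the stress factor ATF3 by 3.66 ± 0.11. Of 56 other DNA repair genes 30 fell and 6 rose, also adjusted over the list alone (median -0.31, or -0.62 with median scaling; adjusted p = 9.74e-04), with NTHL1 at -1.79 ± 0.13 and PARP2 at -1.66 ± 0.10.

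A further 4 lists were past the threshold and lost it with an estimated correlation. Replication genes fell in 33 of 57 and rose in 11, also adjusted over the list alone (median -0.33, or -0.62 with median scaling; adjusted p = 0.0396; adjusted p = 0.229 with an estimated correlation). Their call ended without siFOXM1 replicate 3 (adjusted p = 0.0530) or replicate 1 of siFOXM1 with doxorubicin (adjusted p = 0.0713) and with a filter at the 75th percentile (adjusted p = 0.108). ASF1B and TK1 still rose, by 2.43 ± 0.11 and 1.98 ± 0.09, while CDCA7, a regulator of DNA methylation, fell by 1.85 ± 0.12 and RFC4 by 0.90 ± 0.10. Homologous recombination and Fanconi anaemia genes fell in 17 of 32 and rose in 2 (18 and 2 adjusted over the list alone; median -0.33, or -0.51 with median scaling; adjusted p = 0.00260; adjusted p = 0.0707 with an estimated correlation), with NBN at -1.70 ± 0.12, BARD1, the partner of BRCA1, at -1.60 ± 0.09 and FANCG at -1.34 ± 0.09. Interferon-stimulated genes rose in 22 of 37 and fell in 4, also adjusted over the list alone (median 0.50, adjusted p = 1.65e-05; adjusted p = 0.0548 with an estimated correlation), with IFI6 at 2.42 ± 0.10, and under median scaling 14 rose, 8 fell and the median was 0.12. Ribosomal protein genes fell in 17 of 35 and rose in 2, also adjusted over the list alone (median -0.25, or -0.51 with median scaling; adjusted p = 0.0271; adjusted p = 0.0923 with an estimated correlation), with RPS7 at -1.96 ± 0.10 and RPL5 at -1.05 ± 0.08. That call also ended with the filter at the 75th percentile (adjusted p = 0.0897).

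**Figure D3:**
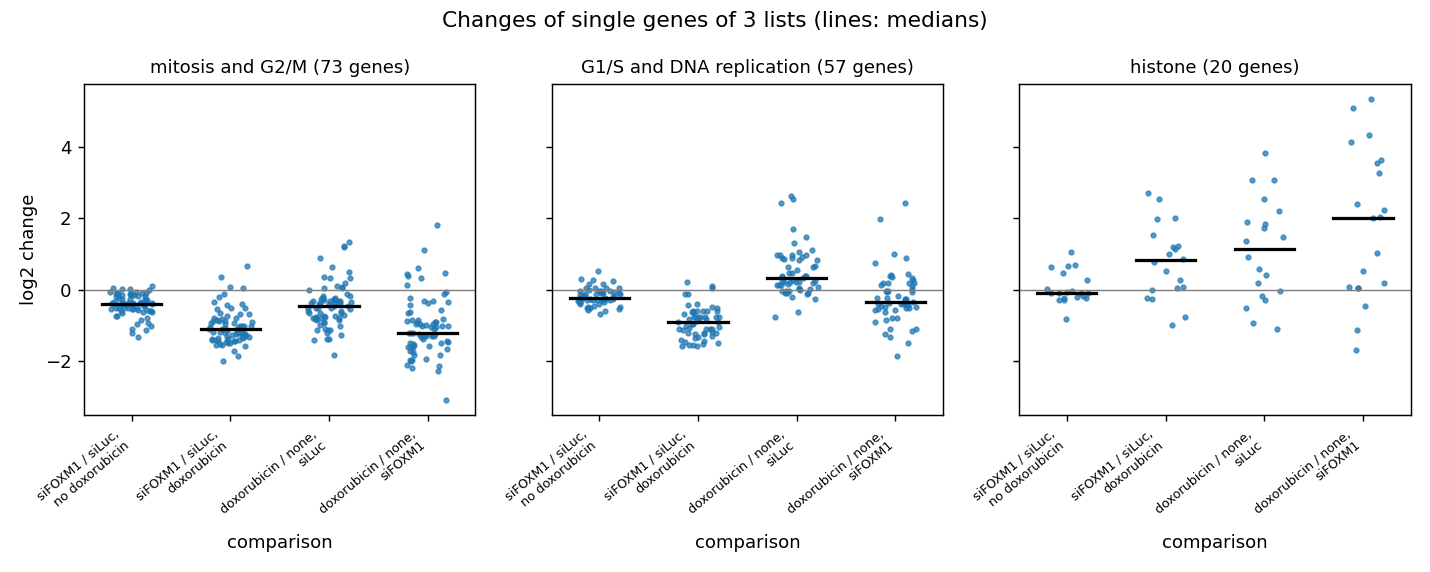
Log2 change of each measured gene (points) of the mitosis and G2/M, G1/S and DNA replication and histone lists in 4 comparisons, with medians as lines. The replication median was -0.22 and -0.91 for siFOXM1 without and with doxorubicin, and 0.34 (0.02 with median scaling) and -0.33 for doxorubicin in siLuc and siFOXM1 cells.

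The largest rises in siFOXM1 cells were H4C8, H2BC21, FOSB, RELN (4.78 ± 0.10), ID2 (4.44 ± 0.14) and the glutathione transferase GSTM3 (4.37 ± 0.12). The largest falls were SYDE1 (-3.25 ± 0.09), GPSM1 (-3.21 ± 0.13), DLGAP5, the peroxidase GPX8 (-3.06 ± 0.10), TAMM41 (-3.04 ± 0.11) and MPP4 (-2.91 ± 0.09). Past the threshold were 8720 genes, 4193 higher and 4527 lower, and 1941 changed at least 2-fold (895 higher, 1046 lower). Of those past it 48.1% were higher, against 25.8% of 8026 with median scaling, and the groups did not overlap for 58.3% of genes, where chance gives 10%. The doxorubicin effects in siLuc and siFOXM1 cells correlated across genes at 0.871 (Pearson) and 0.816 (Spearman). Both rose for 3162 genes and both fell for 3313, where independent lists would share 1135 and 1186, and 116 and 48 genes went opposite ways.

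**Figure D4:**
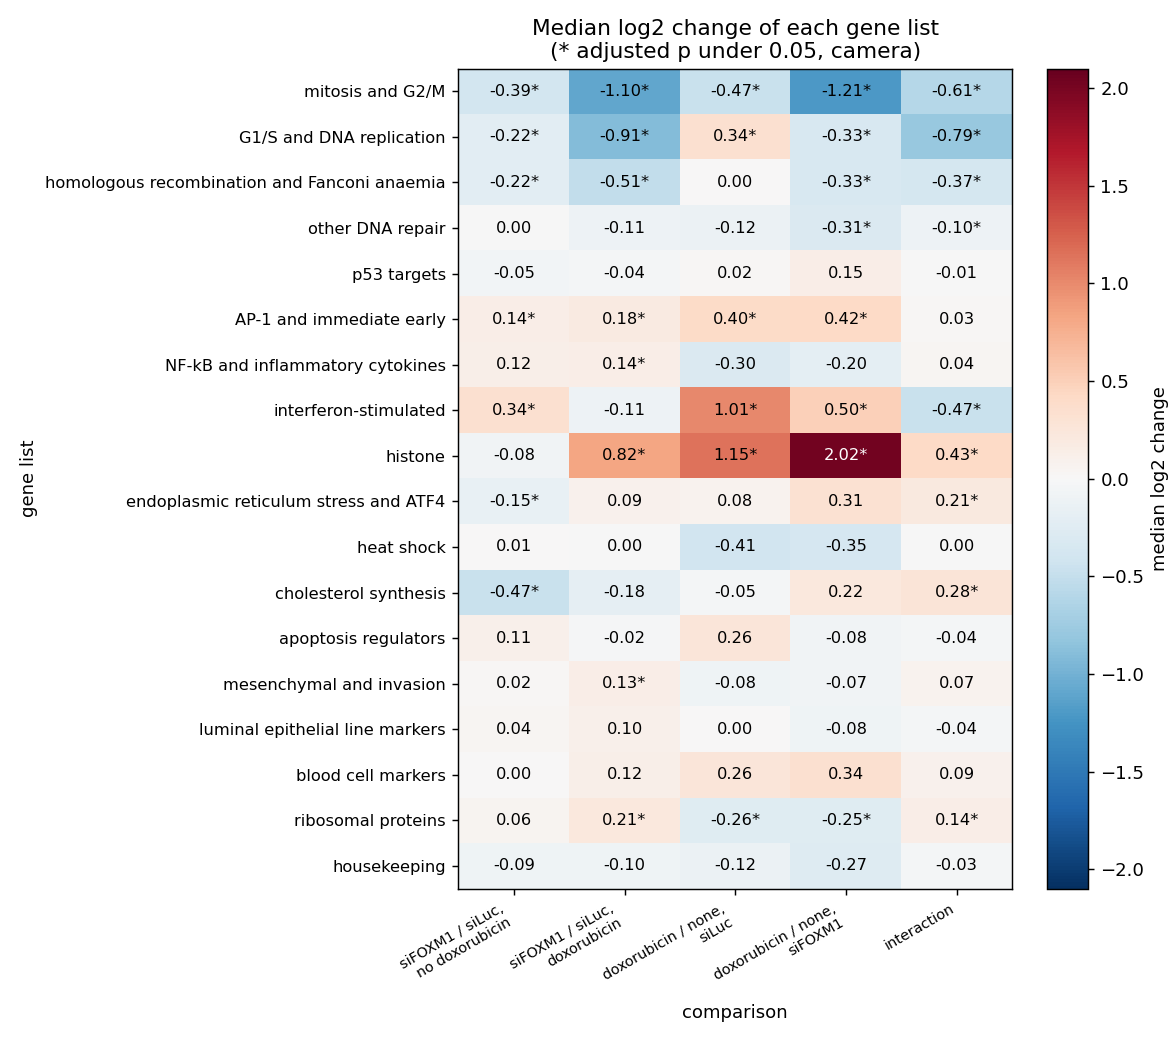
Median log2 change of the 18 gene lists (vertical axis) in the 5 comparisons (horizontal axis), coloured by value, with a star where the camera test was past the threshold. With median scaling, which shifts all genes, 22 of these 90 medians changed sign, 3 of them where the test was past the threshold in one or both settings and each by less than the median of all genes (-0.0966 and -0.132): AP-1 (-0.04) and mesenchymal genes (-0.02) for siFOXM1 with doxorubicin, and p53 targets (-0.05) for doxorubicin in siFOXM1 cells.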

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

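The tests of overall signal, of FOXM1 acting on mitotic genes alone and of S phase were chosen after the results they bear on had been seen, as were the classes of histone genes and the permutation of residuals. The siFOXM1 effect differed with and without doxorubicin, by the interaction test, in 2220 genes. Lists whose interaction was past the threshold were mitosis (median -0.61 log2), replication (-0.79), homologous recombination and Fanconi anaemia (-0.37), other DNA repair (-0.10), interferon-stimulated (-0.47), histone (0.43), endoplasmic reticulum stress (0.21), cholesterol synthesis (0.28) and ribosomal protein genes (0.14; adjusted p = 0.0998 with an estimated correlation). Single genes were KRTAP3-2 (2.67), H4C5 (2.31), H4C8 (2.26), MMP3 (2.08) and H3C10 (2.05) upward, and CACNA2D3 (-1.81), E2F2 (-1.65), S1PR5 (-1.64), SBSN (-1.55) and MPP4 (-1.55) downward. Of 100 splits of the 12 arrays into 4 groups of 3, 1, the real one, gave as many as 2220 genes, and the highest other gave 1756. Such splits move the doxorubicin effect into the spread or into the interaction, so they do not tell whether chance can be excluded. The residuals of the arrays were then permuted with the separate effects of siFOXM1 and doxorubicin kept. Of 100 orders 1, the real one, gave as many genes, and the highest other gave 0. This excluded the spread between these arrays as the source of the count, at a share under 0.05. It does not cover the spread between cultures, since the 3 samples of a group may be technical.

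Mitosis and replication genes fell more with siFOXM1 under doxorubicin than without it. Both lists fell more than genes of like intensity: random lists had interaction medians of -0.126 to 0.0655 (central 95%) for mitosis and -0.130 to 0.0694 for replication, and the smaller gap of both lists below these was -0.479 log2. This cannot decide whether lower overall signal of the siFOXM1 arrays with doxorubicin played a part. Quantile normalization keeps medians of random lists near 0 whatever the signal, and both lists were taken up for their interactions. A single array was argued against, since the replication median without any 1 of the 3 siFOXM1 arrays with doxorubicin came no closer to 0 than -0.759 (-0.788 with all). FOXM1 acting on mitotic genes alone stays open: replication genes fell under doxorubicin with a median of -0.908, but that fall is part of the pattern, and a different share of cells in each phase of the cycle, which was not tested, could also lower them. Effects of the siFOXM1 transfection other than loss of FOXM1 cannot be told apart here either.

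Histone genes rose with doxorubicin in both transfections, though not all did. Of 20, 13 rose and 4 fell in siLuc cells, and 13 rose and 3 fell in siFOXM1 cells. More cells in S phase may contribute in siLuc cells, where 5.26% of replication genes fell, but with median scaling the replication median there was 0.02. In siFOXM1 cells 57.9% of replication genes fell and 11 of 57, ASF1B and TK1 among them, rose. The median was -0.33 against -0.240 to 0.175 for random lists of like intensity. This does not tell whether more cells were in S phase there, since siFOXM1 itself lowered 52 of the 57 under doxorubicin (median -0.91). The call of the replication list for doxorubicin in siFOXM1 cells was also lost with an estimated correlation (adjusted p = 0.229), with a filter at the 75th percentile (adjusted p = 0.108) and without siFOXM1 replicate 3 (adjusted p = 0.0530) or replicate 1 of siFOXM1 with doxorubicin (adjusted p = 0.0713). Poly(A) tails on transcripts of clustered histone genes, which normally lack them, cannot be told apart from a rise in transcription: 17 clustered genes had a median of 1.49 and 8 stand-alone ones 0.15 in siLuc cells, a difference of 1.34 with a permutation p of 0.0605, which so few genes leave open. In siFOXM1 cells the medians were 2.22 and -0.22, with 4 of the 8 stand-alone genes lower, and that difference (2.45) was not tested.

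Among 3275 tested probes without a gene symbol, which the comparisons left out, 63 and 194 were past the threshold for siFOXM1 without and with doxorubicin, and 380 and 455 for doxorubicin in siLuc and siFOXM1 cells. What they measure was not worked out.

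For the 4 comparisons of 3 arrays with 3, the 10 splits of the 6 arrays were too few for a share under 0.05. In each, 1 split, the real one, gave as many genes (2670, 5124, 8441 and 8720), and the highest other gave 0.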

How the results depend on the processing

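An offset of 16, a filter at the 75th percentile, and leaving out arrays for gene lists and correlations were chosen after seeing the data. Detection p-values as a filter and slides as a block were not run, since the deposited table held neither, and an offset of 50 in place of 16 was already the setting used. After normalization the replicate numbers showed no pairing of the samples: same-number arrays correlated at -0.137 to 0.0723 after group means were removed and different-number arrays at -0.0911 to 0.107. Before it, replicate 3 had the lowest mean intensity of each group (438 in siLuc, 392 in siFOXM1, and 384 and 325 with doxorubicin). Normalization takes such differences out, so a pairing of the samples by number stays open. With the numbers as a replicate block, 2489, 5036, 8331, 8639 and 2120 genes were past the threshold, in the order of siFOXM1 without and with doxorubicin, doxorubicin in siLuc and siFOXM1 cells, and the interaction.

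FOXM1 kept its direction and its call under every alternative run, at -2.42 to -2.07 without and -2.60 to -2.15 with doxorubicin. Counts of genes stayed within 1.5 times of those reported except at a fold of at least 1.5, which by construction gave 571, 1650, 4186, 4551 and 1222, and for the interaction with median scaling (967). Without 1 array the counts ran from 1836 to 3173, 4346 to 5066, 7691 to 8854, 8024 to 8685 and 1675 to 2511. Spearman correlations of the effects were 0.458 and 0.839 with median scaling, and 0.374 to 0.412 and 0.797 to 0.824 without 1 array.

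Of 1795 values of the 90 list results under alternatives, 1678 kept direction and side of the threshold, 26 were no longer past it, 17 were newly past it and 74 changed sign. Of those 74, the 3 named first under median scaling were past the threshold in one or both settings, and the others in neither. The cause was not tested except where a setting's construction gives it. No list changed its sign or its call without background correction, with an offset of 16, with the series table or with the replicate block. An estimated correlation leaves medians as they are and ended the calls of AP-1 genes for siFOXM1 without (0.14) and with doxorubicin (0.18), NF-kB (0.14) and mesenchymal genes (0.13) for siFOXM1 with it, mitosis genes for doxorubicin in siLuc cells (-0.47), replication (-0.33), homologous recombination (-0.33), interferon-stimulated (0.50) and ribosomal protein genes (-0.25) for doxorubicin in siFOXM1 cells, and ribosomal protein genes for the interaction (0.14).

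Median scaling shifts all genes (medians -0.0825, -0.0966, -0.116 and -0.132 in the first 4 comparisons), so a turn smaller than that shift is no fall relative to all genes. Some lists shifted by more than that, so a larger turn may be part of the shift as well. Median scaling turned AP-1 (-0.0423) and mesenchymal genes (-0.0207) for siFOXM1 with doxorubicin, and p53 targets (-0.0505) for doxorubicin in siFOXM1 cells. Of lists past the threshold in neither setting it turned, for siFOXM1 without doxorubicin, heat shock (-0.23), apoptosis (-0.0120), mesenchymal (-0.0785), luminal (-0.0167) and ribosomal protein genes (-0.12), and with it endoplasmic reticulum stress (-0.0871), luminal (-0.12) and blood cell genes (-0.11). For doxorubicin in siLuc cells it turned homologous recombination (-0.19), p53 (-0.0553), endoplasmic reticulum stress (-0.21), apoptosis (-0.0697) and luminal genes (-0.15), and in siFOXM1 cells endoplasmic reticulum stress (-0.0211) and cholesterol synthesis genes (-0.13). For the interaction it turned p53 (0.0014), AP-1 (-0.0255), heat shock (0.0294) and housekeeping genes (0.0784). It ended the calls of AP-1 genes for siFOXM1 without doxorubicin (0.0496) and NF-kB genes with it (0.0328), with no turn of sign. The call of AP-1 genes with doxorubicin, whose median turned, ended too. Newly past the threshold were housekeeping genes for siFOXM1 without doxorubicin (-0.25), other DNA repair (-0.23) and cholesterol synthesis (-0.29) for siFOXM1 with it, and other DNA repair (-0.43) and heat shock genes (-0.77) for doxorubicin in siLuc cells. So were p53 targets for doxorubicin in siFOXM1 cells, whose median turned. With median scaling and an estimated correlation together, a pair looked at after the data were seen, the smallest adjusted p of the 90 camera tests was 0.311, so no list call held. Mitosis genes for siFOXM1 with doxorubicin were among the lists at 0.311, with 67 of 73 lower, 1 higher and a median of -1.29. Why the pair was so strict was not tested.

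Without a filter, other DNA repair was newly past the threshold for siFOXM1 with doxorubicin (-0.11) and for doxorubicin in siLuc cells (-0.12), as were p53 targets for doxorubicin in siLuc (0.0204) and siFOXM1 cells (0.15) and endoplasmic reticulum stress genes in the latter (0.31). With the filter at the 75th percentile, AP-1 genes for siFOXM1 without doxorubicin (0.15, adjusted p = 0.0745), mesenchymal genes with it (0.14, adjusted p = 0.0694), and replication (-0.35) and ribosomal protein genes (-0.25) for doxorubicin in siFOXM1 cells lost their calls, and other DNA repair for siFOXM1 with doxorubicin gained one (-0.20). Of lists past the threshold in neither setting, the signs of other DNA repair (0.0020) and luminal genes (-0.0186) for siFOXM1 without doxorubicin, luminal genes with it (-0.0035), cholesterol synthesis genes for doxorubicin in siLuc cells (0.0970) and luminal genes in siFOXM1 cells (0.28) turned.

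Without 1 array, the lists whose calls changed ran as follows. For siFOXM1 without doxorubicin AP-1 genes had 0.12 to 0.18. For siFOXM1 with it NF-kB genes had 0.10 to 0.18, mesenchymal genes 0.0807 to 0.14 and other DNA repair -0.14 to -0.0789. For doxorubicin, other DNA repair in siLuc cells had -0.15 to -0.11, and in siFOXM1 cells p53 targets had 0.0736 to 0.17 and replication genes -0.33 to -0.25. For the interaction, ribosomal protein genes had 0.0760 to 0.15 and mesenchymal genes 0.0374 to 0.0970. Lists that changed sign without a call in any setting of this kind had, for siFOXM1 without doxorubicin, -0.0310 to 0.0363 (other DNA repair), -0.0497 to 0.0433 (heat shock), -0.0052 to 0.0486 (luminal) and -0.0820 to 0.0383 (blood cells), and with it -0.0454 to 0.0698 (heat shock), -0.0487 to 0.0179 (apoptosis) and -0.00063 to 0.12 (luminal). For doxorubicin in siLuc cells they had -0.0769 to 0.0519 (homologous recombination), -0.0055 to 0.18 (endoplasmic reticulum stress), -0.0746 to 0.0132 (cholesterol synthesis) and -0.0405 to 0.0473 (luminal), and in siFOXM1 cells -0.16 to 0.0015 (luminal). For the interaction they had -0.0504 to 0.0305 (p53), -0.0098 to 0.0844 (AP-1), -0.0666 to 0.0843 (NF-kB), -0.0361 to 0.0234 (heat shock) and -0.0974 to 0.0279 (housekeeping).

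Of 4244 values of the 186 gene changes named, 4232 kept direction and side of the threshold, 10 were no longer past it and 1 was newly past it. The remaining 1, RFC4 for doxorubicin in siLuc cells, which was not past the threshold, changed sign without siLuc replicate 1 (0.0249) and ran from -0.13 to 0.0249 without 1 array. For dim genes, signal near the background limits what can be seen.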

Other observations

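The test of gene length was chosen after the largest falls had been seen. p53 targets showed strong single responses to doxorubicin without a list call. In siLuc cells 14 of 33 rose and 6 fell (median 0.02, and -0.0553 with 10 higher and 7 lower under median scaling; adjusted p = 0.125), with the growth factor family member GDF15 at 2.09 ± 0.09 and BTG2 at 1.40 ± 0.10. The cell cycle inhibitor CDKN1A rose by 2.59 ± 0.09 at the probe used and stood at 0.20 at another. In siFOXM1 cells 12 rose and 6 fell (median 0.15, and -0.05 with 7 higher, 8 lower and adjusted p = 0.0443 under median scaling; adjusted p = 0.0599), with GDF15 at 3.43 ± 0.09 and an interaction of 1.34 ± 0.13 for it. Without replicate 1 of siFOXM1 or of siFOXM1 with doxorubicin that list was past the threshold (adjusted p = 0.0427 and 0.0383). For siFOXM1 the list had medians of -0.05 (adjusted p = 0.625) and -0.04 (adjusted p = 0.989), with the cyclin CCNG1 at -1.18 ± 0.10 without doxorubicin.

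Under doxorubicin in siLuc and siFOXM1 cells, NF-kB genes had medians of -0.30 (adjusted p = 0.320) and -0.20 (adjusted p = 0.686), or -0.52 and -0.47 under median scaling, with the chemokine CCL5 at 2.98 ± 0.12 and the growth factor CSF2 at -1.70 ± 0.10 in siLuc cells. Apoptosis regulators had 0.26 (adjusted p = 0.548) and -0.08 (adjusted p = 0.989), or -0.0697 and -0.34 under median scaling, with TNFRSF10D at 1.89 ± 0.10, PMAIP1 at 1.67 ± 0.11 and BCL2L1 at -1.29 ± 0.12 in siLuc cells. Heat shock genes had -0.41 (adjusted p = 0.147, and 0.0485 with median scaling) and -0.35 (adjusted p = 0.397), though HSPA1B rose by 1.56 ± 0.09 in either. Endoplasmic reticulum stress genes had 0.08 (adjusted p = 0.798) and 0.31 (adjusted p = 0.0648), or -0.21 and -0.0211 under median scaling, with the stress factor DDIT3 at 2.59 ± 0.10 and 2.68 ± 0.10. Cholesterol synthesis genes had -0.05 (adjusted p = 0.519) and 0.22 (adjusted p = 0.463, and -0.13 under median scaling), with DHCR7 at -1.92 ± 0.10 in siLuc cells and HMGCS1 at 2.20 ± 0.10 in siFOXM1 cells. Mesenchymal genes had -0.08 (adjusted p = 0.593) and -0.07 (adjusted p = 0.989), or -0.36 and -0.23 under median scaling, with SERPINE2 at 2.37 ± 0.09 and PLAU at -2.36 ± 0.10 in siLuc cells.

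Markers and reference genes were short of the threshold in all 5 comparisons with quantile normalization. For doxorubicin in siLuc cells, luminal markers had a median of 0.00 (adjusted p = 0.779, and -0.15 under median scaling), with KRT19 at -0.92 ± 0.11, blood cell markers 0.26 (adjusted p = 0.651), with CD14 at 2.17 ± 0.11, and housekeeping genes -0.12 (adjusted p = 0.634), with POLR2A at 3.07 ± 0.09 and ACTB at -1.35 ± 0.10. For siFOXM1 without doxorubicin, histone genes had -0.08 (adjusted p = 0.798), other DNA repair 0.00 (adjusted p = 0.779), heat shock genes 0.01 (adjusted p = 0.590, and -0.23 under median scaling), apoptosis regulators 0.11 (adjusted p = 0.214, and -0.0120 under median scaling), ribosomal protein genes 0.06 (adjusted p = 0.147, and -0.12 under median scaling) and housekeeping genes -0.09 (adjusted p = 0.119, and 0.00772 with median scaling). Mesenchymal genes had an interaction of 0.07 (adjusted p = 0.0852), past the threshold without siLuc replicate 3 of the doxorubicin group (adjusted p = 0.0477). Median, mean and test differed in sign for other DNA repair, histone and heat shock genes for siFOXM1 without doxorubicin, for p53 targets, interferon-stimulated and heat shock genes with it, for housekeeping genes and luminal markers for doxorubicin in siLuc cells, for apoptosis and mesenchymal genes in siFOXM1 cells, and for p53 targets, heat shock genes and blood cell markers in the interaction.

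SMYD3, among the largest falls with doxorubicin in siLuc cells, was taken from general knowledge as a very long gene. Such genes may lose transcripts where the drug stops elongation. A list of other very long genes was written from general knowledge as well, leaving out any seen among the largest falls. Of 48 measured, 35 fell and 1 rose in siLuc cells (median -0.578 log2), against -0.105 to 0.118 for the central 95% of random lists of like intensity. In siFOXM1 cells 30 fell and 0 rose (median -0.419, random lists -0.118 to 0.109). This went with the explanation, but RELN, itself very long and not in the list, rose by 4.12 ± 0.10, and lengths were not measured.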
